A study of Mus musculus with 4 samples.

How the data were processed

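The series measured TFE3 binding in a mouse macrophage cell line by ChIP-seq after cross-linking in 1% formaldehyde, per the labels' protocols. The 4 libraries were IgG background, TFE3 control, TFE3 starvation and TFE3 LPS, with 1 library in each group; the group of each came from its description in the labels. The submitters' processing notes name Bowtie (a read aligner), MACS2 (a peak caller) and the build mm9, without versions; filters on reads, the handling of duplicates and the cut-off for peaks are not given in the sources used here. Each list holds the peaks of 1 TFE3 library called against the IgG library, per the file names and peak names, and no libraries were pooled.

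Each deposited peak has a start, an end and a summit position, taken here as the layout MACS2 writes, with starts counted from 0; positions are printed counted from 1. The score deposited for each peak was found to be 10 times its -log10 q value, truncated. The fold enrichment in each list is the ratio of the TFE3 pileup to the expected pileup at the summit, as the authors' peak caller gave it, per the file headers. The -log10 p and -log10 q values are the authors' own as well, per the file headers. Peaks were ranked by -log10 q within a list, with ties broken by chromosome and start. No chromosome had a peak beyond its end in mm9, while 8 of 22 chromosomes had one beyond the end in mm10 (GenomeInfoDb 1.38.1, R 4.3.3).

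The lists state no read depth. It was estimated from the columns themselves: MACS2 computes fold as pileup plus 1 over expected pileup plus 1, and p from a Poisson law at the expected pileup. Peaks whose expected pileup equals the genome-wide background share a ladder of p values that fixes that background, and the steps of their folds give the value of 1 read after scaling to the smaller library. The background was fitted on the 6 most frequent p values of each list. In control 49.4% of peaks lay on that ladder, in starvation 36.0% and in LPS 43.3%, and all of these gave a whole number of reads within 0.05. The step was 0.626, 0.940 and 0.899, and the background with the minimum peak width as the extension and the default mouse genome size of MACS2 (1.87e+09 bp, assumed) gave 26.9 M IgG reads from each of the 3 lists separately. The TFE3 depths follow from the steps: 43.0, 28.7 and 30.0 M reads (M for mega). Ratios between them do not need the genome size. The same relations gave the reads at the summit for all control and starvation peaks and for all but 5 LPS peaks; their medians were 39, 27 and 30 reads. On lists simulated from the same relations, with known reads, background and step, all summit reads were recovered. This checks the solving step and not the relations. Simulated peaks with a low ratio of pileup to expected pileup were left out.

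Lists were compared by overlap of at least 1 bp. Overlap counts equalled those of bedtools 2.31.1 in all 6 ordered pairs, and 500 planted shared peaks were all found in each simulated pair. Shares have exact Clopper-Pearson 95% intervals and summit reads exact Poisson intervals; reads without molecular identifiers are not independent molecules, so both cover counting error only. Each overlap of whole lists stands beside 100 random placements of the same widths within each chromosome's span, which assume that peaks could lie anywhere. All 3 lists share the IgG library, so part of an overlap may come from it, and this cannot be simulated from peak lists; among the 961 control peaks at the genome-wide background, where the local IgG reads do not enter, 961 had an LPS peak and 926 (96.4%, 95.0 to 97.5) a starvation peak. Equal-sized lists took the 1944 highest-scoring peaks of each. Merged sites were the union of overlapping peaks of the 3 lists. Peaks per Mb used the span from the first to the last peak of a chromosome. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

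The rule for named peaks, fixed before the data were examined, took the 5 highest-scoring peaks of each list and the 5 highest-scoring peaks of each treatment with no control peak; any other named peak is said to be chosen after its values were seen. Starvation and LPS summit reads were compared as RPM (reads divided by the estimated depth in M reads), with an exact binomial interval. The proportion between libraries was the ratio of summed summit reads above background, and its deviation the squared residuals over their Poisson variance, per degree of freedom. Alternatives were a stricter score, merging of peaks within 500 bp, chromosomes 1 to 19 and X alone, no peaks over 5 kb, other definitions of overlap and other list lengths. Gene names, the planned counts of genes with a peak within 5 kb of a start, the planned gene lists (lysosome, vacuolar ATPase, autophagy, cytokines and others), genomic location and E-box content were not analysed here, since the gene table used here is of another build and no genome sequence was used.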

Results

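TFE3 binding was mapped by chromatin immunoprecipitation and sequencing in a mouse macrophage cell line. TFE3 is a basic helix-loop-helix leucine zipper factor of the MITF/TFE family, known for binding E-box elements near lysosomal and autophagy genes. The question behind the comparisons was where the factor binds in untreated macrophages, without nutrients and in the innate immune response to a bacterial product. The series held 4 libraries: a TFE3 pull-down from untreated control cells, a TFE3 pull-down from cells starved for 2 h in EBSS (a balanced salt solution), a TFE3 pull-down from cells given 1 µg/ml LPS (lipopolysaccharide, a component of the bacterial outer membrane) for 24 h, and an IgG pull-down as the background. Each TFE3 library came with 1 peak list, called against the IgG library. There was 1 library per condition, so no difference between conditions was tested, and every interval given here covers counting error only. The depth was recovered from the steps in the deposited fold and p columns, assuming the default mouse genome size of MACS2: an estimated 43.0 M reads for control, 28.7 M for starvation, 30.0 M for LPS and 26.9 M for IgG. Peaks are named by their position on the mouse build mm9, without gene names. Scores and folds of single peaks are the authors' own values and served to rank and describe peaks within a list. Beyond that, folds entered the estimates of depth and summit reads, and a score cut was applied to all lists as an alternative.

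Both treatments had far more TFE3 peaks than untreated cells. The control list held 1944 peaks, the starvation list 14073 and the LPS list 18220. Starvation thus had 7.24 times and LPS 9.37 times as many peaks as control, and LPS had 1.29 times as many as starvation. Control peaks covered 416 kb of the genome, starvation peaks 4679 kb and LPS peaks 5064 kb. The control library, with the fewest peaks, was the deepest: starvation had an estimated 0.666 times and LPS 0.696 times its reads.

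Starvation peaks were the widest by the median of the whole lists. At the 7143 starvation peaks that overlapped an LPS peak the order turned, with a median of 296 bp against 316 bp in LPS. Of these, 39.6% were wider than their LPS partner. The next values are for whole lists, starvation first. The median width of starvation peaks was 294 bp (quartiles 234 and 378), against 262 bp for LPS (quartiles 223 and 315) and 208 bp for control (quartiles 176 and 240). Peaks over 500 bp made up 10.6% of the starvation list (1485 peaks), 1.27% of the LPS list (232 peaks) and 0.154% of the control list (3 peaks). Of the peaks over 1 kb, 66 were in the starvation list, 2 in the LPS list and 0 in the control list. The widest starvation peak lay at chromosome 14, 123030999 to 123032703 (1705 bp, 52 summit reads), where neither other list had a peak; it was chosen after its values were seen. The narrowest peaks were 145 bp in control, 194 bp in starvation and 193 bp in LPS, so the control widths started from a lower minimum.

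**Figure D1:**
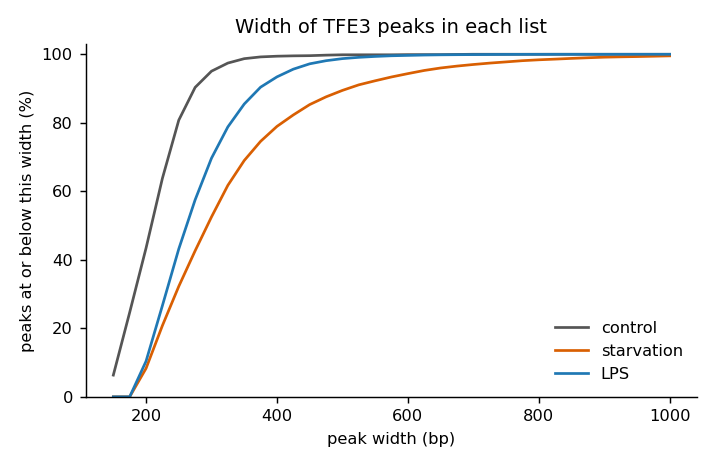
Cumulative share of peaks (%) at or below each width (bp), with 1 line per list. The control line rises first (median 208 bp), the LPS line next (262 bp) and the starvation line last (294 bp), with 10.6% of starvation peaks over 500 bp.

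Nearly all control sites were also called in starvation, and most starvation peaks had no control peak. No call in a list does not show that a site was unbound. Of the 1944 control peaks, 1888 overlapped a starvation peak by 1 bp or more, which is 97.1% (95% exact Clopper-Pearson interval 96.3 to 97.8). Of the 14073 starvation peaks, 1886 overlapped a control peak (13.4%, 12.8 to 14.0) and 12187 did not. Random placements of the control peaks reached 0.617% overlap with the starvation list at most. The 56 control peaks without a starvation peak were all called in the LPS list and lay mostly among the weaker control peaks: the share found in the starvation list was 93.6% in the lowest and 100% in the highest of 4 equal score classes. The strongest of these 56, chosen after its values were seen, lay at chromosome 10, 126398947 to 126399154, with 39 summit reads in control. In the starvation list, the share with a control peak was 1.05% in the lowest score class and 30.3% in the highest.

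The highest-scoring starvation peak lay at chromosome 17, 27836289 to 27837326, with a fold of 44.1 over IgG and 177 reads at the summit (exact Poisson interval 152 to 205). The next 4 lay at chromosome 5, 123097500 to 123098751 (249 summit reads), chromosome 5, 104475093 to 104475979 (178), chromosome 7, 52721886 to 52722621 (195), and chromosome 14, 73002531 to 73003363 (173). All 5 had a control and an LPS peak. The 5 highest-scoring starvation peaks with no control peak lay at chromosome 18, 47157313 to 47158070, chromosome 11, 69804350 to 69805126, chromosome 9, 58826503 to 58827311, chromosome 9, 62885743 to 62886370, and chromosome 11, 60590692 to 60591651. They ranked 6, 10, 22, 40 and 41 in the starvation list, with 302, 205, 181, 137 and 149 summit reads, and each had an LPS peak. At the chromosome 18 peak the expected pileup was 8.23 times the genome-wide background, so its fold over IgG was 11.9.

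Every control site was also called in LPS, and these lay mostly among the strongest LPS sites. All 1944 control peaks overlapped an LPS peak (100%, 99.8 to 100), against at most 0.823% in random placements. Of the 18220 LPS peaks, 1942 overlapped a control peak (10.7%, 10.2 to 11.1) and 16278 did not. The overlap was concentrated at the top of the LPS list. The highest-scoring 500 LPS peaks all had a control peak, while the share over the 4 score classes was 0% (0 of 4555), 0.0659%, 0.220% and 42.3% from lowest to highest. Among the highest-scoring 500 starvation peaks, 256 (51.2%, 46.7 to 55.7) had a control peak.

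The highest-scoring LPS peak lay at chromosome 6, 54816614 to 54817258, with a fold of 47.2 over IgG and 254 summit reads (224 to 287). It was followed by chromosome 6, 119422687 to 119423279 (226 reads), chromosome 19, 4201444 to 4202180 (266), chromosome 5, 104475265 to 104475869 (219), and chromosome 14, 73002542 to 73003203 (221), and all 5 had a control and a starvation peak. The 5 highest-scoring LPS peaks with no control peak came far down the list, at ranks 518, 529, 608, 645 and 653. They lay at chromosome 15, 97047285 to 97047613 (108 reads), chromosome 6, 53562004 to 53562378 (111), chromosome 1, 41476930 to 41477343 (104), chromosome 12, 78317508 to 78318088 (153), and chromosome 3, 20963442 to 20963878 (102), and each had a starvation peak.

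The control list was led by the peak at chromosome 5, 104475340 to 104475803, with a fold of 23.0 and 115 summit reads (94.9 to 138). The same region held the peak ranked 3 in starvation and 4 in LPS. The next control peaks lay at chromosome 1, 90137253 to 90137596 (173 reads), chromosome 7, 52722033 to 52722385 (127), chromosome 9, 64300571 to 64300935 (122), and chromosome 19, 4201582 to 4201892 (130). All 5 were called in both treatments.

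**Figure D2:**
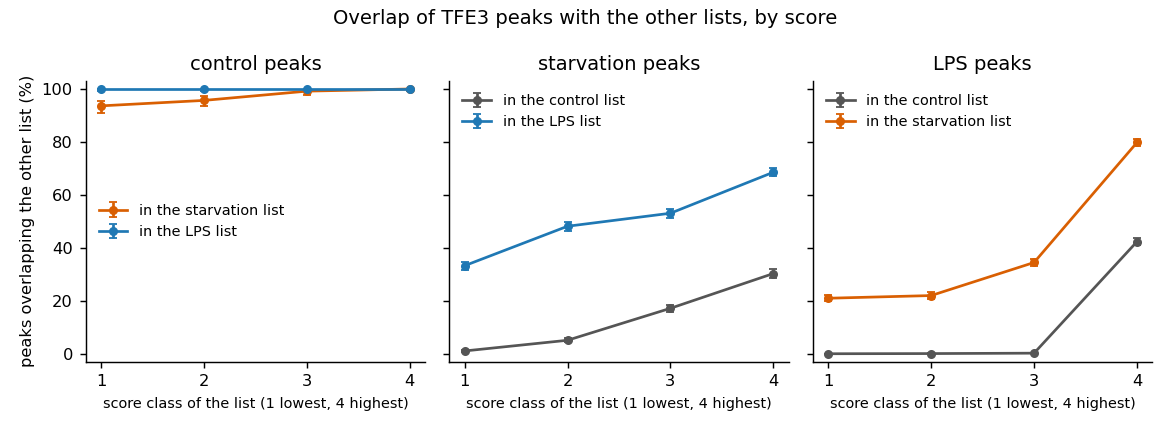
Share of peaks (%) that overlap a peak of another list by 1 bp or more, over the 4 score classes of the list named above each panel, with exact 95% intervals as bars. Control peaks are found in both treated lists at every score (93.6% or more), while the share of LPS peaks in the control list goes from 0.220% in the score class below the highest to 42.3% in the highest.

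Starvation and LPS shared only part of their sites. Of the starvation peaks, 7143 (50.8%, 49.9 to 51.6) overlapped an LPS peak, and of the LPS peaks, 7161 (39.3%, 38.6 to 40.0) overlapped a starvation peak, against at most 0.618% and 0.510% in random placements. After merging, the 3 lists made 25130 sites, of which 6930 were called in starvation alone, 11003 in LPS alone, 5255 in both treatments but not in control, and 1886 in all 3 lists. The remaining 56 were called in control and LPS, and none in control alone. The shared share rose with score: from 33.2% to 68.6% of starvation peaks and from 21.0% to 79.8% of LPS peaks between the lowest and the highest score class. At shared sites, the summits of both treatments lay a median of 15 bp apart, where summits drawn uniformly within the same peaks lay 97.2 bp apart. The uniform draw makes no allowance for summits that lie near the centre of a peak.

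**Figure D3:**
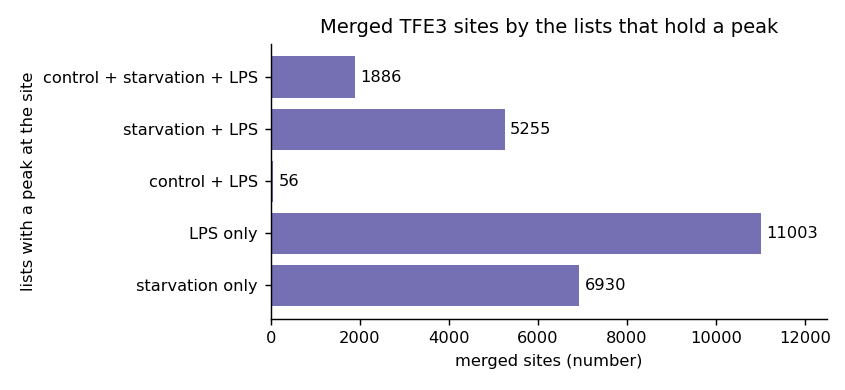
Number of merged sites by the lists that hold a peak there. Sites of LPS alone (11003) and starvation alone (6930) outnumber the 5255 sites of both treatments and the 1886 sites of all 3 lists.

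Strong peaks without a partner in the other treatment were found in both lists, with more of them in starvation at every equal rank examined. Among the highest-scoring 500 of each list, 42 starvation and 0 LPS peaks had no partner, and among the highest 1000, 157 and 1. Among the highest-scoring 1944 starvation peaks, 466 had no LPS peak, and among the same number of LPS peaks, 42 had no starvation peak. Among the highest 5000 of each list the counts were 1749 and 1157, and in the highest of the 4 score classes 1106 of 3518 and 920 of 4555. Only in the whole lists, of 14073 and 18220 peaks, was the order the other way, with 6930 and 11059. These counts, the peaks named next and the read comparison after them were chosen after the data were examined. The strongest starvation peaks with no LPS peak lay at chromosome 18, 82137580 to 82138751 (121 summit reads), chromosome 10, 88041168 to 88042016 (108), and chromosome 9, 51982637 to 51983363 (139), and 0 of the 5 strongest had a control peak. That is not particular to these 5 and was nearly set in advance, since every control peak had an LPS peak. None of the 6930 starvation peaks without an LPS peak had a control peak. The strongest LPS peaks with no starvation peak lay at chromosome 7, 27630729 to 27631133 (94 reads), chromosome 8, 44481164 to 44481534 (89), and chromosome 6, 92821272 to 92821653 (86). Of the 5 strongest of this kind, 3 had a control peak, and the chromosome 6 peak did not.

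At 7141 sites called in both treatments, summit reads scaled to depth (RPM) were lower in starvation at most sites: the median log2 ratio of starvation to LPS was -0.55, with 5th and 95th percentiles of -1.58 and 1.18. The exact interval lay below 0 at 3046 sites, above 0 at 816 and held 0 at 3279. The region most in favour of starvation, chromosome 11, 59622481 to 59623808, had 105 summit reads in starvation and 18 in LPS, a log2 ratio of 2.61 (1.88 to 3.42). The next, chromosome 8, 107934342 to 107935428, had 166 and 31 reads (log2 2.49, 1.93 to 3.09), and neither had a control peak. The region most in favour of LPS, chromosome 7, 139120390 to 139120613, had 20 reads in starvation and 107 in LPS (log2 -2.36, -3.12 to -1.66), and a control peak. With 1 library each, these intervals compare the libraries and not the conditions, and a summit is the highest point of its own list's peak.

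With list length made equal, control overlapped LPS far more than starvation. Among the 1944 highest-scoring peaks of each list, 1638 control peaks (84.3%, 82.6 to 85.9) overlapped an LPS peak, 658 (33.8%, 31.7 to 36.0) overlapped a starvation peak, and 631 starvation peaks (32.5%, 30.4 to 34.6) overlapped an LPS peak. Control and LPS also had the greatest overlap of the 3 pairs with 500 peaks per list (72.0%), with 1000 (76.7%) and when the overlap had to reach 50% of both peaks (52.3%). In the whole lists that last rule turned the order: 80.3% of control peaks then had a starvation partner and 58.7% an LPS partner. The LPS peaks at control sites were wider (median 396 bp) than the starvation peaks there (323 bp), and all 3 lists placed their summits at nearly the same base, a median of 10 bp from control to LPS and 11 bp from control to starvation.

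At the 500 highest-scoring LPS sites, all of which were called in all 3 lists, the control signal was lower than in LPS. Summit reads had a median of 4.54 RPM in LPS (quartiles 4.07 and 5.27), 2.02 in starvation (1.61 and 3.21) and 1.28 in control (1.07 and 1.56). Above the genome-wide background, control reached 0.272 of the LPS RPM (counting SE 0.00198) and starvation 0.509 (0.00341). Control reads followed LPS reads in nearly fixed proportion: their squared deviations from it were 1.20 times the counting variance, where an exact proportion gives 1 with a sampling spread of 0.0633. For starvation against LPS the same value was 5.99. This value measures departure from 1 fixed ratio and not from the order of the sites. By Spearman rank correlation with LPS the 2 libraries were close, at 0.766 for control and 0.736 for starvation. The sites were chosen on their LPS score, which favours LPS, and the order of the treatments turned with that choice: at the 458 of the 500 highest-scoring starvation sites that had an LPS peak, LPS reached 0.873 of the starvation RPM, with a deviation of 17.3. The 42 without an LPS peak were left out, which favours LPS in that value. A summit counts reads over the extension, taken here as the minimum peak width, which in control was 0.751 of that in LPS and lowers the control value, and with 1 library per condition the ratios have no replicate check.

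**Figure D4:**
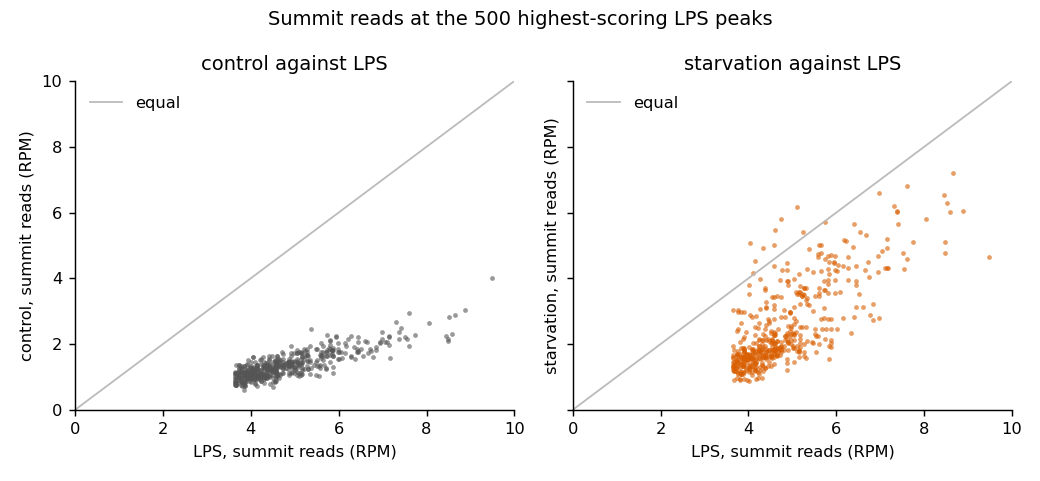
Summit reads scaled to depth (RPM) in control (left) and starvation (right) against LPS at the 500 highest-scoring LPS peaks, 1 point per peak, with a grey line at equal values. Control points lie in a narrow band below the line (0.272 of LPS above background), while starvation points spread widely (0.509 of LPS). The Spearman rank correlations with LPS were close, at 0.766 for control and 0.736 for starvation. At the 458 of the 500 strongest starvation sites that had an LPS peak, the order turned, with LPS at 0.873 of starvation.

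TFE3 peaks were spread over all autosomes and were sparse on chromosome X. Chromosome X made up 6.31% of the span covered by the lists but held 6 control peaks (0.309%, 0.113 to 0.671), 91 starvation peaks (0.647%, 0.521 to 0.793) and 130 LPS peaks (0.714%, 0.597 to 0.847). Autosomes had 21.7 times as many peaks per Mb as chromosome X in control, 10.3 times in starvation and 9.37 times in LPS. Chromosome 9 was the densest in every list, with 1.26 control, 8.94 starvation and 12.1 LPS peaks per Mb. Chromosome 11 was the only autosome with more starvation peaks (961) than LPS peaks (939), and chromosome 14 had the lowest ratio of starvation to LPS peaks (0.652, 488 against 749). These shares were not adjusted for copy number, which was not measured here, or for how much of each chromosome can be mapped.

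**Figure D5:**
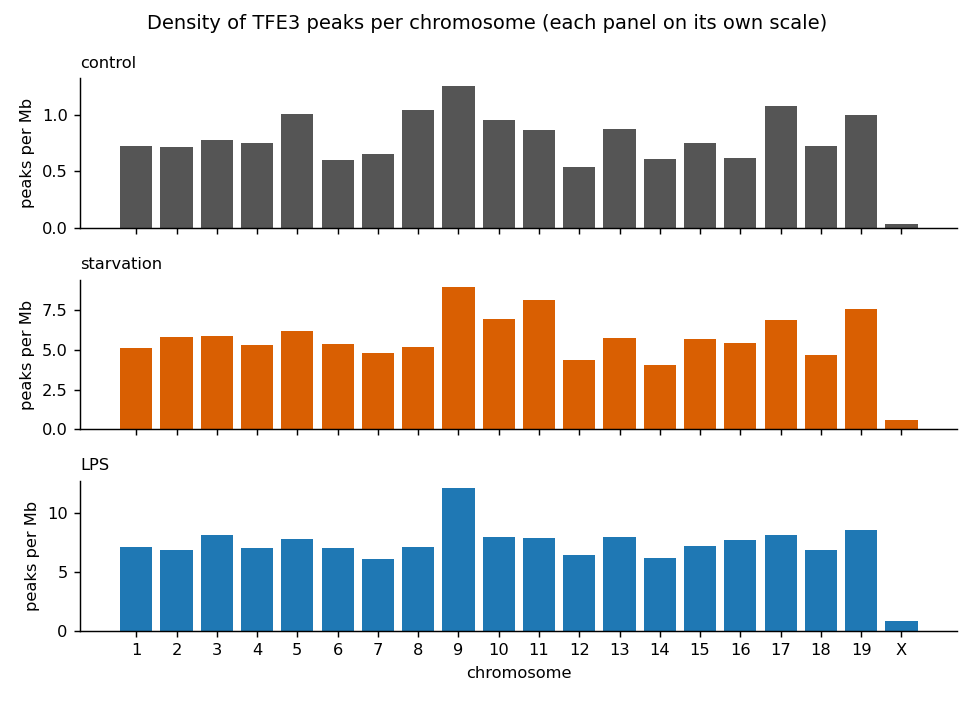
Peaks per Mb on chromosomes 1 to 19 and X, with 1 panel per list, each on its own scale from 0. Chromosome 9 is the highest in each panel (1.26, 8.94 and 12.1 peaks per Mb) and chromosome X the lowest.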

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

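Alternatives named as added here were chosen after the data were examined; the others were fixed before. Leaving out peaks over 5 kb removed no peak and tests nothing. In the other 6 alternatives for peak number and width the control list stayed the shortest with the narrowest median and the LPS list the longest, and starvation kept the widest median; 63 of the alternative values stayed within the main interval, the quartiles of width or 1.5 times the main count, and 29 moved. The moved counts follow from the stricter score itself: at or above each list's own median score, 972 control, 7103 starvation and 9140 LPS peaks were left, and at or above the control median score, 972, 6490 and 10096. With 50% reciprocal overlap, 80.3% of control peaks had a starvation and 58.7% an LPS partner, starvation peaks overlapped control at 11.1% and LPS at 46.8%, LPS peaks overlapped control at 6.27% and starvation at 36.2%, and in the equal-sized lists control overlapped starvation at 22.0% and LPS at 52.3%; peak width enters this rule. With midpoints within 100 bp, control overlapped starvation at 94.1% and LPS at 99.3%, starvation overlapped LPS at 48.6% and LPS overlapped starvation at 37.5%. Starvation overlapped LPS at 52.7% when peaks within 1 kb counted and at 51.9% after merging within 500 bp. In the higher-scoring 50% of each list, control overlapped starvation at 96.2%, starvation overlapped LPS at 47.1% and LPS overlapped starvation at 36.4%. With 500 peaks per list control overlapped LPS at 72.0%; with 1000, control overlapped LPS at 76.7% and starvation at 30.4%, and starvation overlapped LPS at 29.5%. Of the added alternatives, control against the 5000 highest-scoring peaks gave 71.0% in starvation and 99.4% in LPS, while a common p threshold and the removal of peaks with an expected pileup over 5 times background moved no value. Where no construction is named, the cause was not tested. The alternatives for genes at a start, gene lists, genomic location and E-box content were not run, since no annotation or sequence of mm9 was used. No paired analysis was possible because each group had 1 library. The smallest summit had 22 reads in control, the deepest library, 12 in starvation and 15 in LPS, and what sets these values was not tested.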

Other observations

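All tests in this part were chosen after the results were seen. Starvation peaks came in groups more often than chance placement gave. Of the starvation peaks, 30.0% (29.3 to 30.8) lay within 10 kb of another, against 12.6% at most in 100 random placements; in LPS it was 17.3% (16.8 to 17.9) against 15.4%, and in control 2.42% (1.78 to 3.20) against 2.62%. Groups of 5 or more peaks numbered 45 in starvation, 3 in LPS and 0 in control. The starvation groups with the most peaks lay at chromosome 18, 9485302 to 9508694 (11 peaks, 2 in LPS), chromosome 6, 47600680 to 47635473 (10 peaks, 0 in LPS), chromosome 6, 47689783 to 47728368 (9 peaks, 0 in LPS), chromosome 1, 172989336 to 173012148 (8 peaks, 0 in LPS), and chromosome 5, 125870087 to 125889926 (8 peaks, 2 in LPS). The LPS groups with the most peaks lay at chromosome 9, 3051993 to 3068065 (9 peaks, 3 each in control and starvation), and chromosome 16, 32750405 to 32756569 (7 peaks, 2 in starvation).

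A few peaks lay where the expected pileup was over 10 times the background: 2 in control, 8 in starvation and 11 in LPS. They included chromosome 8, 19725694 to 19725890 in control (22.0 times background, fold 2.78), 3 starvation peaks on chromosome 11 between 3062542 and 3081362, and the mitochondrial peak at 11862 to 12218 in starvation (376 summit reads, fold 3.06), whose summit lay at position 12035, against 12036 in LPS.

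The control list was the shortest although its library was the deepest. Lower depth was excluded, since control had 1.44 times the estimated reads of LPS. Reads were scaled for calling, with 1 read worth 0.626 in control and 0.899 in LPS, so the extra control reads did not raise its pileup. A stricter p threshold was excluded as well, but only for a cut at the lowest -log10 p of the control list (5.27). Of 14073 starvation peaks 13956 pass it, and of 18220 LPS peaks 18200. That cut removes few peaks and tests no other calling setting. The smallest summit had 22 reads in control, 12 in starvation and 15 in LPS, and what sets these values was not tested. A lower share of reads at enriched sites stays open. Control had 0.272 of the LPS reads, both scaled to depth and above background at the 500 strongest LPS sites. The shorter extension in control (0.751 of that in LPS) lowers this value in part. It also lowers the pileup on which control peaks were called, and its effect on their number was not tested. A weaker pull-down and less TFE3 on chromatin in untreated cells cannot be told apart with 1 library per condition and no spike-in used here.

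The control peaks lay mostly among the strongest LPS peaks, in close proportion at the 500 strongest, which all had a control peak, while 308 of the 1944 strongest did not. List length did not account for the greater overlap of control with LPS than with starvation. Of the control peaks, 99.4% overlapped the 5000 highest-scoring LPS peaks and 71.0% the same number of starvation peaks. For the place of control peaks among the strongest LPS peaks, the 99.4% restates the pattern and tests no cause. Control reads deviated from a fixed share of the LPS reads by 1.20 times the counting variance, near the 1 that LPS reads or chromatin carried into the control library would give but above it by more than the sampling spread of 0.0633, which leaves carry-over open. The same sites bound at a lower level without treatment could give a close proportion as well, and the 5.99 of starvation against LPS shows that the test can come out otherwise. The 1 for carry-over also presumes the same extension in both lists, whereas that of control was 0.751 of that in LPS. No value here decides between these explanations, and the close proportion makes the control library one to compare with a replicate.

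Strong starvation peaks often lacked an LPS peak, 1106 of 3518 in the highest of 4 score classes. In the same class of the LPS list, 920 of 4555 peaks lacked a starvation peak. Peaks without an LPS peak were not confined to weak starvation peaks near the threshold, since they made up 31.4% of the highest score class. This restates the pattern. The 466 such peaks among the highest 1944 had at least 44 summit reads, which follows from choosing them by score. Whether LPS signal there lay just under its calling level was not tested, and the LPS list reached down to 15 reads. A shifted LPS peak was excluded for most, since 17 of the 466 had one within 1 kb. Broad regions of open chromatin pulled down in the starvation library stay open, with values on both sides: 44.8% (40.3 to 49.5) of the 466 lay within 10 kb of another starvation peak, against 32.7% (30.3 to 35.1) of those with an LPS peak, but their median width was 480 bp against 485 bp. In each of the 4 score classes of the whole starvation list, peaks without an LPS peak were the wider by the median. In the highest class it was 432.5 against 410 bp. TFE3 binding particular to starvation stays open too and was not tested, as 1 library per condition cannot separate it from the library. The treatments also differed in length, with 2 h of starvation against 24 h of LPS, which cannot be told apart from their kind.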
